A study of Homo sapiens with 4 samples.

How the data were processed

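RNA of K562 cells, an established human line grown from a chronic myeloid leukaemia in blast crisis and dependent on the BCR-ABL kinase, was measured on 4 two-colour arrays of 19200 probes. Per the labels, 2 arrays set cells treated with STI571 (imatinib, a BCR-ABL kinase inhibitor) against untreated cells, and 2 set cells given amifostine (AMI, a thiol prodrug used as a cytoprotectant) with STI571 against cells given AMI alone. In each comparison the dyes, Cy5 and Cy3, were exchanged between the arrays, so that 1 array of each pair carried the STI571-treated RNA in Cy5. The labels do not say whether the arrays of a pair came from separate cultures, so the p-values measure the spread between these arrays, which may be technical.

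The deposited values are log2 ratios of the 2 dyes of an array, 1 per probe and array. The log base was read from the values, which stop at 16.61, the log2 of 100000. The scanner, background correction, normalization and direction of the ratio (Cy5 over Cy3 or the opposite) are not given in the sources used here. Signal over background is also unknown, and the number of arrays limits the precision. Medians of the deposited values were 0.283 and -0.267 on STI571 arrays 1 and 2, and 0.226 and -0.032 on AMI+STI571 arrays 1 and 2. The 11 values at the ceiling were set to missing, beside 881 missing as deposited. Each array was then centred on its median.

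The ratios were read by dye, and the array with the treated RNA in Cy3 changed sign. This reading rests on the values: across probes, arrays of the same dye orientation had Spearman correlations of 0.475 and 0.399, and arrays of opposite orientation had -0.28, -0.29, -0.49 and -0.507. The same pattern would arise if the authors had already turned the ratios and a dye bias of single genes outweighed the treatment. A positive ratio below therefore means more RNA in the cells given STI571 if the deposited ratio is Cy5 over Cy3, and less if it is Cy3 over Cy5. Positive and negative name the 2 sides and no direction of change.

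Of the probes, 9416 had 1 gene symbol in the platform annotation, 378 had several and 9406 had none. The Entrez identifiers of 9390 of the first group matched the RefSeq gene table and 26 did not, which changed 0 symbols. Probes with 1 symbol and a value on all 4 arrays were averaged per symbol, and the others, including those with several symbols, were tested alone as probes. This gave 15969 features, of which 6644 were named genes, 1815 of them with more than 1 probe.

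Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) over all 4 arrays, with 1 coefficient per comparison, 2 residual degrees of freedom and 5.44 after moderation. The 4 contrasts were the STI571 ratio without AMI, that with AMI, their difference (with AMI minus without) and their mean. Adjusted p-values are Benjamini-Hochberg values over all features, with a threshold of 0.05. Values are log2 ratios ± SE from the fit. Gene lists, 32 in number and fixed before the data were examined, were tested with camera (preset correlation 0.01), with an estimated correlation and fry as alternatives.

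On simulated data with 15969 features, the mean of both comparisons recovered 52% of genes changed 2-fold and 96% of those changed 4-fold. For STI571 against untreated the shares were 12% and 82%, and for AMI+STI571 against AMI 2% and 82%. For the difference they were 12% at 4-fold and 80% at 8-fold. Each share rests on 50 changed genes, so small gaps between shares mean little. The simulated errors were independent, without effects of dye or position.

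The genes to be named were fixed by rule before the data were examined. For each contrast, the rule took up to 10 genes per side with the largest ratio among those past the threshold and on the same side on every array. For the difference, the 4 arrays had to order without overlap. Where fewer passed, up to 5 per side were filled in by size and are given as values that did not pass. From every list, up to 4 members with the largest absolute moderated statistic for the mean were added, and for the apoptosis lists also up to 4 for the difference. Genes named outside the rule are said to be.

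The alternatives were a dye term (the dye orientation as the replicate block), each array left out, no centring, scaling to 1 median absolute deviation, genes with 1 value per pair, exact zeros as missing, each probe alone, robust and unmoderated statistics, a threshold of 0.1, limma treat at 1.2-fold, a 1.5-fold rule on every array, and the features with the smaller residual spread. With 1 array left out, its comparison rests on 1 dye orientation, so a dye effect no longer cancels there. Chosen after the data were seen were centring of each run of 400 probe numbers, ratios taken as already turned, and neighbouring calls counted once.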

Results

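Gene expression in K562 leukaemia cells was measured to find how amifostine alters the response to STI571, with apoptosis genes as a focus and the interaction of the 2 drugs as the main interest of the design. Both comparisons had 2 arrays of opposite dye orientation, with 18933 to 18997 usable probes per array. The design text speaks of 6 independent paired experiments, and 4 arrays were used here. Positive ratios mean higher RNA with STI571 only if the deposited ratios are Cy5 over Cy3, which the labels do not settle. If they are Cy3 over Cy5, every sign below turns. Each ratio for 1 comparison is the mean of 2 arrays, and each mean over both comparisons rests on 4.

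STI571 was first compared with no treatment. Among apoptosis genes the widest ratios were negative: BCL2L11, which encodes the pro-apoptotic protein BIM, had -1.51 ± 0.56, and BCL2L1, which encodes the anti-apoptotic BCL-XL, had -1.16 ± 0.27. TNFRSF10D, a decoy receptor for the death ligand TRAIL, had -0.88 ± 0.18, and TNFSF10, the gene of TRAIL itself, had 0.33 ± 0.16. Outside apoptosis, GFI1B, an erythroid and megakaryocytic transcriptional repressor, had 1.07 ± 0.17, the succinate dehydrogenase subunit gene SDHC had 1.42 ± 0.18, and the chemokine gene CCL3 had 1.69 ± 0.32. On arrays 1 and 2 BCL2L11 had -2.77 and -0.25, BCL2L1 -1.69 and -0.62, and CCL3 1.04 and 2.335. None of these passed limma's test over all 15969 features. TNFRSF10D, GFI1B, SDHC, CCL3 and the metallothionein gene MT1H (0.82 ± 0.15) passed when adjusted over the list alone.

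For this comparison limma called 0 features, with a smallest adjusted p of 0.0607, while 2754 had an unadjusted p under 0.05 against 798 expected by chance. Of these, 1585 were positive and 1169 negative. Both arrays put 68.5% of features on the same side, where chance gives 50%. Among named genes of 1 sign on both arrays, the largest ratios that did not pass were WAC at 3.02 ± 0.24, PPP1R13B at 2.85 ± 0.42, OAZ2 at 2.44 ± 0.78, ARRDC1 at 2.17 ± 0.16 and KCNH2 at 2.15 ± 0.50. On the negative side they were ENPP5 at -3.70 ± 1.35, PLEKHH2 at -2.85 ± 0.49, DAB2 at -2.61 ± 1.10, CBLL1 at -2.56 ± 0.80 and BBS1 at -2.20 ± 0.71. Several of these were further from 0 on array 2. ENPP5 had -6.81 there and -0.59 on array 1, DAB2 -5.145 and -0.08, CBLL1 -4.395 and -0.73, BBS1 -3.81 and -0.60, PLEKHH2 -3.93 and -1.77, and OAZ2 3.94 and 0.95. Of the 9 measured anti-apoptotic genes, 7 were negative (median -0.21), as were all 3 measured pro-apoptotic BCL2 family genes and 4 of 6 death receptor genes. No list passed camera (smallest adjusted p 0.773, and 0.986 with an estimated correlation). In a fit without 1 array of this comparison, its ratio rests on the other array, where dye and STI571 cannot be told apart. Without array 1 of this comparison limma called 72 features, 37 of them positive, and the heat shock protein list passed camera with a median of -0.60 (adjusted p 0.0349), but not with an estimated correlation (adjusted p 0.908). Without its array 2 limma called 9.

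**Figure D1:**
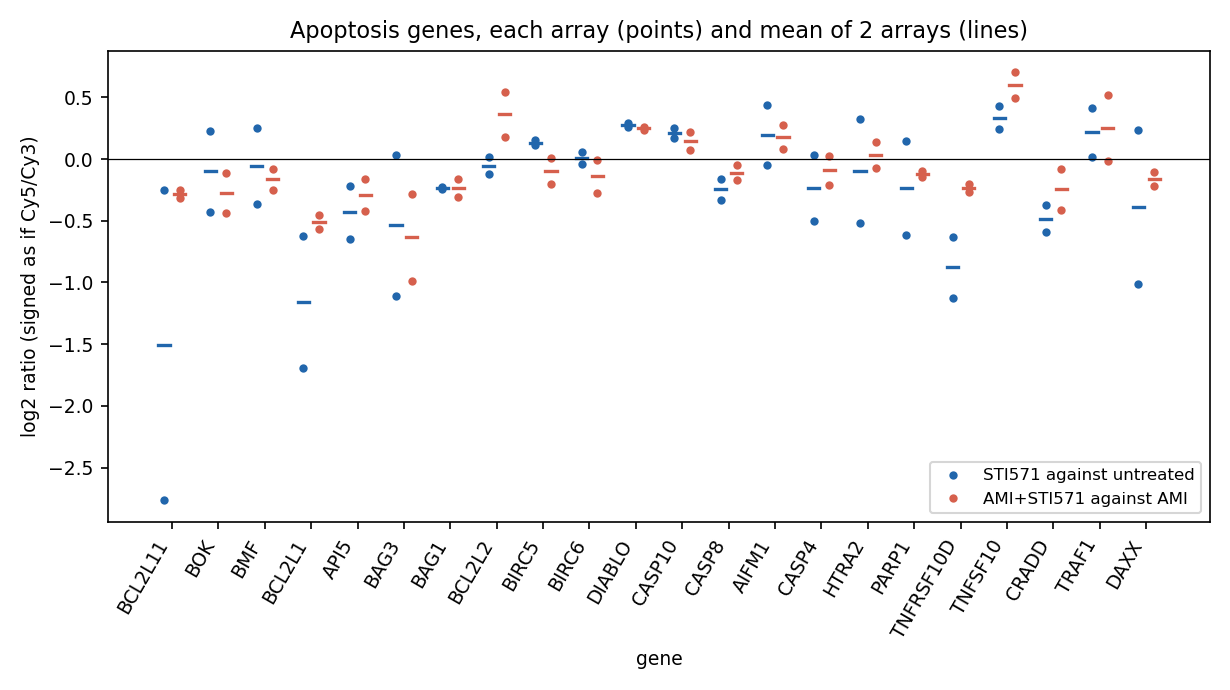
Log2 ratios of the named apoptosis genes on each array (points) and the mean of the 2 arrays of a comparison (lines), signed so that positive means higher with STI571 if the deposited ratio is Cy5 over Cy3. BCL2L11 lies at -2.77 and -0.25 on the arrays without AMI, and at -0.25 and -0.32 on those with AMI.

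The effect of STI571 was then measured in cells that also received AMI. UROD, an enzyme gene of heme synthesis, had 2.02 ± 0.26, MCM5, a subunit of the replicative helicase, had 1.98 ± 0.47, and SDHC had 1.28 ± 0.18. Apoptosis genes had smaller ratios than these, with BCL2L1 at -0.51 ± 0.27, BCL2L11 at -0.28 ± 0.56, TNFRSF10D at -0.23 ± 0.18 and TNFSF10 at 0.60 ± 0.16. Of these apoptosis genes TNFSF10 lay further from 0 than without AMI, and the others nearer. BAG3, a co-chaperone gene with anti-apoptotic function, had -0.63 ± 0.32, with -0.28 on array 1 and -0.99 on array 2. None of these passed over all features, and UROD and SDHC passed when adjusted over the list alone.

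Here limma called 1 feature, the unnamed probe 1284, with 3.25 ± 0.15 (adjusted p 0.0327, positive on both arrays). At an unadjusted p under 0.05 there were 1922 features, 1392 positive and 530 negative, against 798 expected. Both arrays put 59.8% of features on the same side. Among named genes of 1 sign on both arrays, the largest ratios that did not pass were PBRM1 at 4.71 ± 1.77, POLR1D at 4.10 ± 1.41, PPP1R13B at 3.40 ± 0.42, KLRG2 at 3.29 ± 1.28 and WAC at 3.06 ± 0.24. ENC1 at -2.56 ± 0.80, BAHD1 at -1.88 ± 1.35, ACTN2 at -1.63 ± 0.25, KLK5 at -1.62 ± 0.60 and PBXIP1 at -1.50 ± 0.46 lay furthest on the negative side. Several of these rest on 1 array. PBRM1 had 8.71 on array 2 and 0.71 on array 1, KLRG2 6.245 and 0.325, ENC1 -4.39 and -0.74, BAHD1 -3.74 and -0.01, and KLK5 -2.96 and -0.28. On array 1 POLR1D had 7.335 and PBXIP1 -2.48, against 0.87 and -0.51 on array 2. Of the 9 anti-apoptotic genes 8 were negative (median -0.17), as were 6 of 7 p53 targets (median -0.26) and 7 of 8 heat shock protein genes (median -0.24). No list passed camera (smallest adjusted p 0.427, and 0.993 with an estimated correlation). The call of probe 1284 was lost when any 1 of the 4 arrays was left out, with a dye term, scaled arrays, 1 value per pair, unmoderated statistics or run centring, and with ratios taken as already turned. Without array 1 of this comparison limma called 5 other features.

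The mean of both comparisons, over 4 arrays, gave the most calls. WAC, an adaptor gene linked to histone H2B ubiquitination, had 3.04 ± 0.17 (adjusted p 0.0149), and ARRDC1, an arrestin domain gene, had 2.12 ± 0.12 (adjusted p 0.0149). CYB5R2, a cytochrome b5 reductase gene, had 1.84 ± 0.14, and TOR1AIP2, whose product activates torsin ATPases, had 1.69 ± 0.14, both with an adjusted p of 0.0406. All 4 genes were positive on 4 of 4 arrays. With a dye term in the model CYB5R2 (adjusted p 0.093) and TOR1AIP2 (adjusted p 0.0704) lost their calls, while WAC and ARRDC1 kept theirs. WAC lost its call with run centring (adjusted p 0.0701), ARRDC1 with scaled arrays (adjusted p 0.0537), and CYB5R2 and TOR1AIP2 with both, 1 value per pair and treat. All 4 lost theirs with unmoderated statistics (adjusted p 0.272) and with ratios taken as already turned. All 4 genes also lost their calls in 3 of the 4 fits that left out 1 array, and kept them only without STI571 array 1. Their ratios moved little in these fits, to 2.87 to 3.20 for WAC, 2.06 to 2.18 for ARRDC1, 1.72 to 1.97 for CYB5R2 and 1.55 to 1.83 for TOR1AIP2. The other 12 calls were unnamed probes, 11 positive and 1 negative. That 1, probe 919, had -2.42 ± 0.15 without AMI and -0.08 ± 0.15 with it.

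In all, limma called 16 features for the mean, 15 positive and 1 negative. At an unadjusted p under 0.05 there were 3917, against 798 expected, and 36.9% of features lay on the same side on all 4 arrays, where chance gives 12.5%. PPP1R13B, which encodes a p53-binding protein, had 3.13 ± 0.30 and missed the threshold (adjusted p 0.0637). So did, among named genes of 1 sign on all 4 arrays, PBRM1 at 2.95 ± 1.25, POLR1D at 2.49 ± 0.999, OAZ2 at 1.93 ± 0.55 and KCNH2 at 1.85 ± 0.36. On the negative side ENC1 had -1.79 ± 0.56, PLEKHH2 -1.67 ± 0.34, CBLL1 -1.66 ± 0.57, PLEKHA7 -1.61 ± 0.63 and CFAP44 -1.35 ± 0.53, none of which passed. Without AMI+STI571 array 2 the mean was 0.95 for PBRM1 and -0.88 for ENC1, and without array 1 of that comparison 0.87 for POLR1D. Without STI571 array 2 it was 1.18 for OAZ2, -0.75 for CBLL1 and -0.78 for PLEKHA7, and without STI571 array 1 -0.52 for CFAP44. Probes next in number to called ones were often positive as well. Of 28 such probes 23 were above 0, with a median of 0.36 against 0.004 for all probes. Of the 16 calls, 11 had another probe above 1 within 2 numbers. The unnamed probe before WAC had 3.10, and CCL3, 2 numbers before WAC, had 1.46. PPP1R13B stood beside unnamed probes at 1.27 and 1.92. With ratios taken as already turned, 0 features were called. Leaving out 1 array gave 75 calls (without STI571 array 1, 14 of them among the 16), 7 (without AMI+STI571 array 1, 1 among the 16), 0 (without AMI+STI571 array 2) or 3 (without STI571 array 2, 2 among the 16). Centring of runs of 400 probes gave 5.

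**Figure D2:**
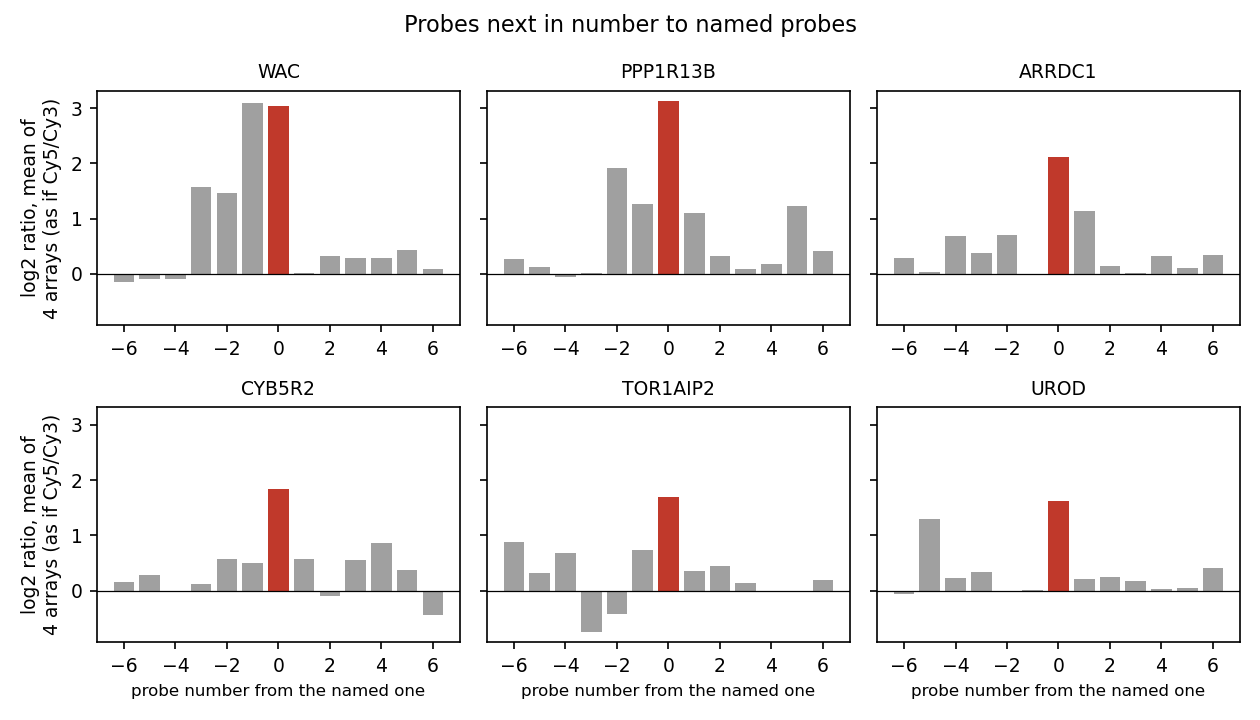
Mean log2 ratio over 4 arrays of the probes up to 6 numbers from the named probe (red), signed so that positive means higher with STI571 if the deposited ratio is Cy5 over Cy3. The probes 1 to 3 numbers before WAC had 3.10, 1.46 and 1.56, and the probe after it had 0.02.

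Erythroid genes, which K562 cells express, had 17 positive and 12 negative members in the mean over both comparisons. UROD (1.61 ± 0.18) and GFI1B (0.83 ± 0.12) passed when adjusted over the list alone, while CPOX, another gene of heme synthesis, had -0.39 ± 0.11 and HBA1, an alpha globin gene, 0.30 ± 0.11. Glycolysis genes were positive in 8 of 12, with ALDOA at 0.70 ± 0.20 (0.43 without STI571 array 2), GPI at 0.45 ± 0.11, TPI1 at 0.43 ± 0.12 and PFKP at 0.41 ± 0.13. Of 21 oxidative phosphorylation genes 12 were positive, and SDHC (1.35 ± 0.13) passed when adjusted over the list alone, while COX4I1 had 0.62 ± 0.15 over 3 probes that disagreed in sign. Heat shock protein genes were negative in 7 of 8, with HSPA6 at -0.51 ± 0.13 and HSPA8 at -0.48 ± 0.21 (-0.24 without AMI+STI571 array 1). In the integrated stress response and unfolded protein response 9 of 14 were negative. HERPUD1, an endoplasmic reticulum stress gene, had -0.65 ± 0.13 and passed when adjusted over the list alone, and DDIT3, which encodes CHOP, had -0.52 ± 0.14, while PDIA4 had 0.27 ± 0.12 (0.18 without AMI+STI571 array 1).

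Most apoptosis lists held more negative than positive members, and none passed camera. The anti-apoptotic genes were negative in 7 of 9, with BCL2L1 at -0.83 ± 0.19, BAG3 at -0.59 ± 0.23 (-0.30 without STI571 array 2), API5 at -0.36 ± 0.13 and BAG1 at -0.23 ± 0.11. All 3 pro-apoptotic BCL2 family genes were negative, with BCL2L11 at -0.90 ± 0.40, or -0.27 without STI571 array 1. Death receptor genes were negative in 4 of 6, and TNFRSF10D (-0.56 ± 0.13) and TNFSF10 (0.47 ± 0.11) passed when adjusted over the list alone, on opposite sides. The 7 genes of caspases and the apoptosome split into 3 positive and 4 negative, with DIABLO, an antagonist of the inhibitors of apoptosis, at 0.26 ± 0.10 and CASP8 at -0.18 ± 0.11. p53 targets were negative in 6 of 7, with CCNG1 at -0.55 ± 0.15, although RRM2B had 0.66 ± 0.17 (0.43 without AMI+STI571 array 1). FOXO targets split 4 and 4, with INSR at 0.30 ± 0.12 and GADD45A at -0.26 ± 0.13 (-0.16 without STI571 array 1). Targets of BCR-ABL, ERK and STAT5 were positive in 8 of 18, with CCND3 at -0.38 ± 0.11, SPRY4, a feedback inhibitor of ERK signalling, at -0.39 ± 0.11 and CCND1 at 0.36 ± 0.11 over 3 probes that disagreed in sign.

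Cell cycle lists went both ways. G1/S and DNA replication genes were positive in 5 of 12, with MCM5 at 1.32 ± 0.33 (0.85 without STI571 array 1). The probes 1 and 2 numbers after that of MCM5 had 0.60 and 1.35, and the probe before it -0.10. MCM6 had 0.36 ± 0.11 over 2 probes that disagreed in sign, TYMS -0.34 ± 0.12 and PCNA -0.29 ± 0.10. G2/M genes were positive in 8 of 14, with CCNA2 (cyclin A) at -0.64 ± 0.18 and CENPF at -0.34 ± 0.11, against BUB3 at 0.32 ± 0.125 and CKS1B at 0.26 ± 0.11. Growth arrest genes were positive in 4 of 9, with CDKN1C at 0.48 ± 0.23 (0.16 without AMI+STI571 array 1) and RBL1 at -0.25 ± 0.11. DNA repair genes were positive in 4 of 13, and MGMT, which removes alkyl groups from guanine, had 0.95 ± 0.18 and passed when adjusted over the list alone. BLM had 0.66 ± 0.195 (0.44 without STI571 array 2), OGG1 -0.375 ± 0.11 and APEX1 -0.34 ± 0.10. Of 4 histone genes 2 were positive, and H1-2 (0.68 ± 0.18, or 0.44 without AMI+STI571 array 1) passed when adjusted over the list alone, while H2BC21 had -0.48 ± 0.33 and 0.03 without AMI+STI571 array 1. AMI was on both sides of 1 comparison and on neither side of the other, so the mean does not measure a response to the thiol drug. Thiol and oxidative stress genes split into 10 positive and 13 negative in the difference between the comparisons. In the mean, 14 of 23 were positive. The cystine transporter gene SLC7A11 had -0.47 ± 0.16 (-0.30 without AMI+STI571 array 2), and GSR, glutathione reductase, had 0.42 ± 0.16 (0.22 without AMI+STI571 array 1). Metallothionein genes were positive in 3 of 4, and MT1H (0.68 ± 0.10) passed when adjusted over the list alone.

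Further lists had similar splits. Autophagy and lysosome genes were negative in 11 of 16, and ATG7 (-0.87 ± 0.17) and ULK1 (0.71 ± 0.16), both needed for autophagosome formation, passed when adjusted over the list alone on opposite sides. NF-kB targets were positive in 7 of 12, and CCL3 (1.46 ± 0.22) passed when adjusted over the list alone, while RELB had -0.42 ± 0.12. Drug transport genes split 2 and 2, and ABCC2, an export pump gene, had 0.61 ± 0.12 and passed when adjusted over the list alone. Cytosolic ribosomal proteins split 12 and 12, ribosome biogenesis genes were positive in 8 of 11, interferon genes in 7 of 11, cholesterol synthesis genes in 5 of 11 and amino acid transport and tRNA synthetase genes in 7 of 13. Housekeeping genes were positive in 4 of 7, and megakaryocytic genes in 7 of 10. Markers of other cell types were positive in 7 of 10 for myeloid cells, 4 of 6 for lymphocytes and 8 of 14 for fibroblasts, epithelium and endothelium.

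Of 370 memberships in the 32 lists, 13 passed adjusted over the list alone for the mean and 0 passed over all features. No list passed camera (smallest adjusted p 0.565, and 0.979 with an estimated correlation). The directional fry test called 0 lists (smallest adjusted p 0.329), while its mixed test called 13, that is, lists whose members differed from 0 in either direction. That test does not compare a list with the other features. By limma 83 of the 370 memberships had an unadjusted p under 0.05, and 3917 of all 15969 features. List members thus reached it no more often than features in general, and the mixed calls do not set these lists apart. In 8 lists the median, the mean and the camera direction differed in sign: caspases, G1/S, G2/M, growth arrest, cholesterol synthesis, NF-kB targets, drug transport and DNA repair. Without centring the median of all features moved from 0.01 to -0.19, and all ratios are relative to the array medians. Run centring took HERPUD1 to -0.40, BAG3 to -0.33, TNFRSF10D to -0.305, HSPA6 to -0.26, SPRY4 to -0.24, CCND3 to -0.21, CENPF to -0.18, RELB to -0.17 and BAG1 to -0.14. It took TPI1 to 0.28, PDIA4 to 0.18 and BUB3 to 0.175.

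**Figure D3:**
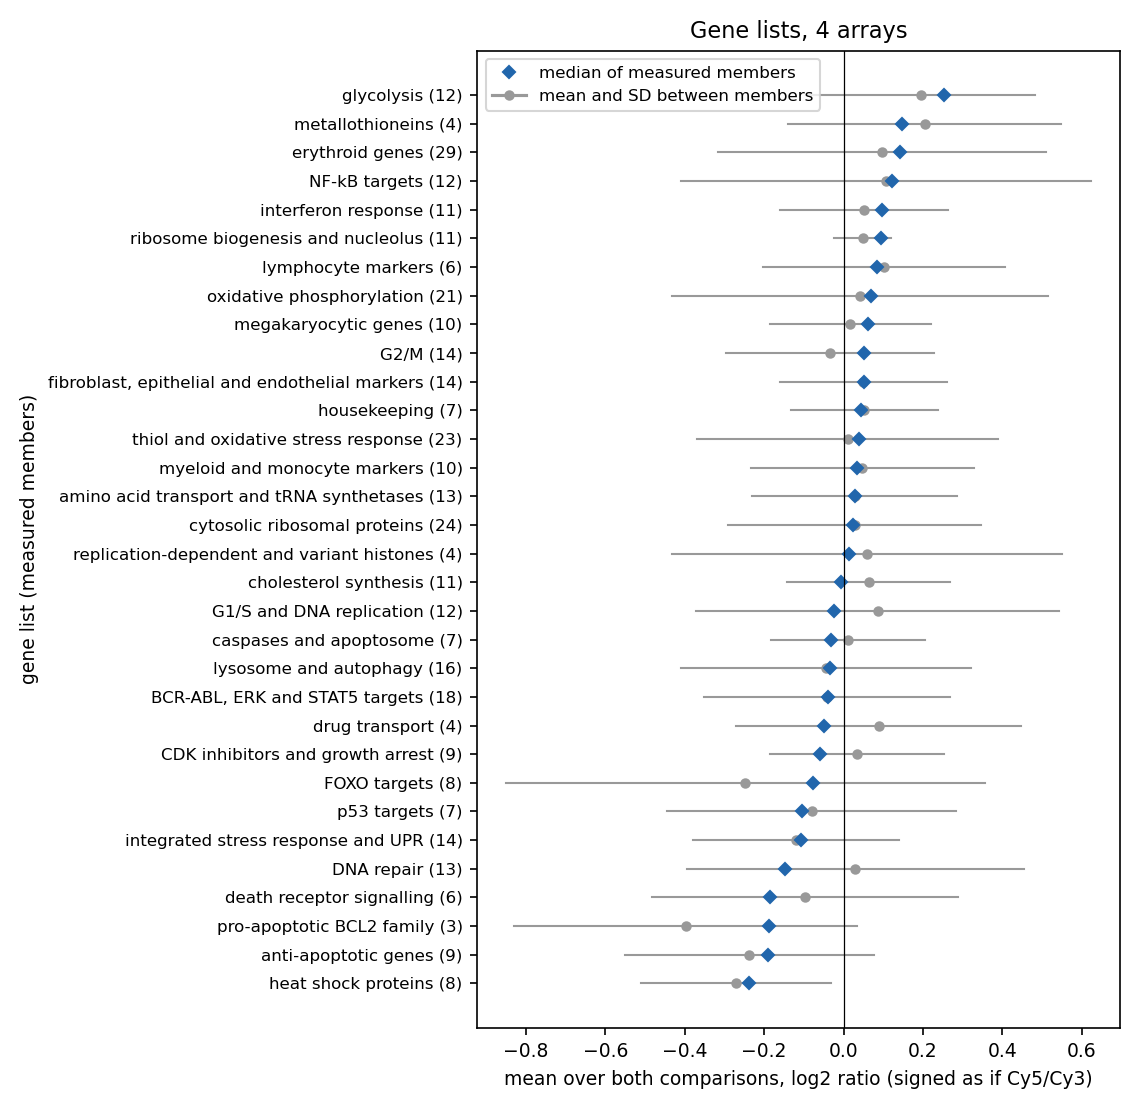
Mean STI571 log2 ratio over both comparisons (4 arrays) for the 32 gene lists, as the median of the measured members (diamonds) and their mean with the SD between members (circles and lines), signed as if the deposited ratio were Cy5 over Cy3. Medians run from -0.24 for heat shock proteins to 0.25 for glycolysis, and no list passed camera.

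The STI571 ratios with and without AMI were related across features. WAC had 3.02 without AMI and 3.06 with it, ARRDC1 had 2.17 and 2.07, and SDHC had 1.42 and 1.28. These genes were picked by the mean of both comparisons, which favours like ratios, so they are no evidence of agreement. Pearson's r was 0.524 and Spearman's rho 0.586 over 15969 features, which are not independent replicates, and 71.9% had the same sign. Of the features with an unadjusted p under 0.05 by limma, 720 were positive in both comparisons, where independent lists would share 138, and 190 were negative in both, against 39. The p-values of a feature in both comparisons share 1 estimate of its spread. The lists are thus not independent even without an effect, and the numbers for independent lists are too low a reference. No RNA group was shared between the comparisons. With ratios taken as already turned, rho was 0.027, and it was 0.384 without AMI+STI571 array 1.

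**Figure D4:**
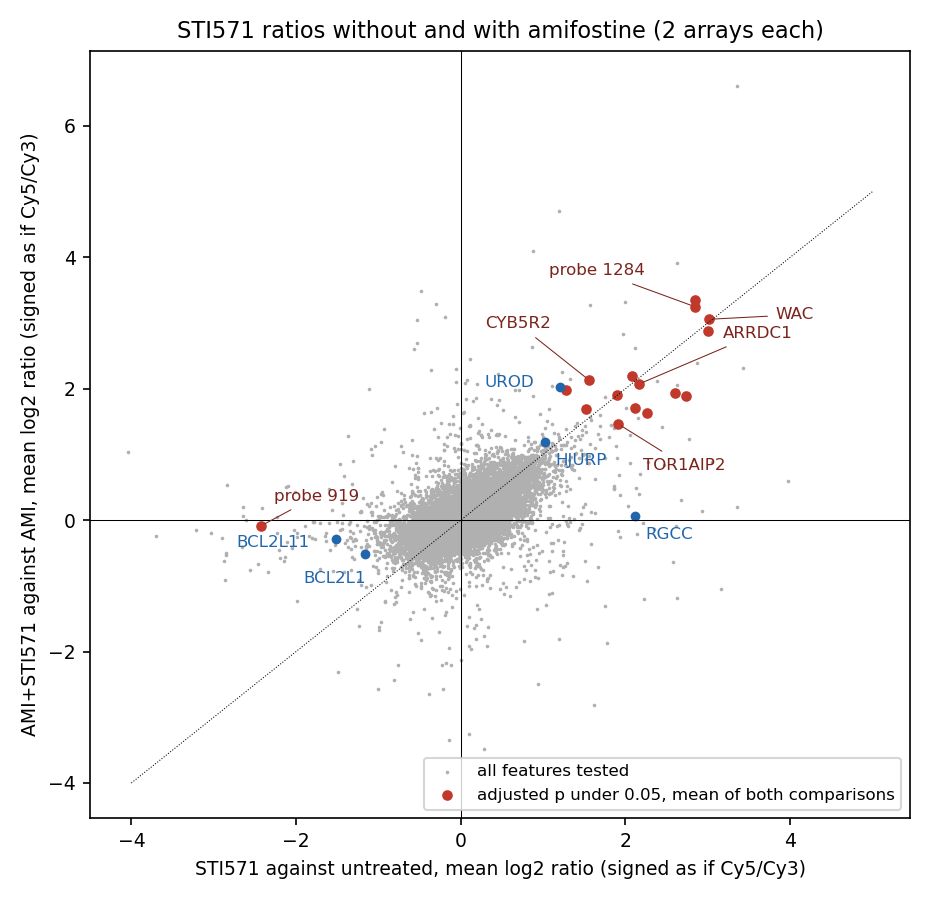
Mean log2 ratio of each feature for STI571 against untreated (x axis) and AMI+STI571 against AMI (y axis), 2 arrays each, signed so that positive means higher with STI571 if the deposited ratio is Cy5 over Cy3. The 16 features with an adjusted p under 0.05 for the mean are red, genes named in the text are blue, and the dotted line marks equal ratios. WAC lies at 3.02 and 3.06, and RGCC at 2.11 and 0.06.

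The difference between the ratios with and without AMI addresses the interaction of the drugs. RGCC, a regulator of the cell cycle, had 2.11 ± 0.17 without AMI and 0.06 ± 0.17 with it, a difference of -2.05 ± 0.24. HPGD, which encodes a prostaglandin-degrading enzyme, had 0.93 ± 0.32 and -1.36 ± 0.32, a difference of -2.29 ± 0.45, with -2.015 and -0.705 on the 2 arrays with AMI. Among apoptosis genes the differences were 1.23 for BCL2L11, 0.65 for BCL2L1 and 0.64 for TNFRSF10D, each nearer 0 with AMI, and 0.41 for BCL2L2. Those of BCL2L11 and BCL2L1 rest on STI571 array 1, without which they were -0.03 and 0.11, and that of TNFRSF10D was 0.40 without STI571 array 2. That of BCL2L2 was 0.23 without AMI+STI571 array 2. None of these differences passed limma's test (adjusted p for RGCC 0.999). The 2-array means of all features also spread less with AMI (median absolute deviation 0.297) than without it (0.348), so a ratio nearer 0 is not particular to apoptosis genes. On arrays 1 and 2 the deviation over probes was 0.446 and 0.282 with AMI, and 0.402 and 0.418 without it. The smaller spread was thus not shared by both arrays with AMI and does not show that AMI narrows the ratios.

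For the difference limma called 0 features (smallest adjusted p 0.868, for probe 919). An unadjusted p under 0.05 was reached by 412, fewer than the 798 expected by chance. The 95% interval lay within 2-fold either way for 69.2% of features, and its median reach on either side was 0.64. All 7 measured p53 targets had a negative difference (median -0.24), but the 4 arrays ordered without overlap for 0 of them. Of 6 death receptor genes 5 had a positive difference (median 0.23), and 2 of the 6 ordered without overlap. Without centring the median difference of all features moved from 0.027 to 0.173. That move of 0.146 is common to all features and smaller than either list median. The size of these list medians therefore depends on the centring, and their sign does not. No list passed camera (smallest adjusted p 0.613, and 0.955 with an estimated correlation). Among named genes whose 4 arrays order without overlap, the largest positive differences were DDX52 at 3.96 ± 2.26, KLRG2 at 3.58 ± 1.81, GATAD2A at 2.65 ± 1.02, CELF4 at 2.63 ± 1.37 and PLEKHH2 at 2.35 ± 0.69. KLK5 (-1.95 ± 0.85), SEMA7A (-1.95 ± 1.13) and TYRP1 (-1.88 ± 0.56) followed HPGD and RGCC on the negative side, under the same limit. Several of these rest on 1 array. DDX52 had 7.19 on AMI+STI571 array 2 and -0.23 on array 1, KLRG2 had 6.245 and 0.325 on the same arrays, and KLK5 fell to -0.61 without that array 2. CELF4 had -4.35 on STI571 array 1 and 0.10 on array 2, SEMA7A had -0.25 and 3.42 on those, and GATAD2A had -1.83 and 1.10. Without STI571 array 2 PLEKHH2 had 1.275 and TYRP1 -1.02. The 4 arrays ordered without overlap for 30.6% of features, where chance gives 33.3%. Without STI571 array 1 limma called 15 features. On simulated data with independent errors this contrast recovered 12% of genes that differed 4-fold, so most interactions of that size or smaller would be missed. The simulation left out variation shared between neighbouring probes or by dye, so that share is only a rough guide to these arrays.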

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

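Run centring, ratios taken as already turned and neighbouring calls counted once were chosen after the data were seen. No direction is claimed for any sign. Groups of 2 arrays are too small for a count of other splits. Array signal over background is unknown, and 4 arrays limit every call. Where an array was left out, the lone array was assumed to vary like the others. Its ratio also holds any dye effect, which 1 array cannot separate from an effect of STI571. The gene list test was not run for genes with 1 value per pair, robust, unmoderated and treat statistics, and the 1.5-fold rule not for the difference. Features of smaller residual spread were used for the correlation only, and neighbouring calls counted once for the mean only. The causes of changes between settings were not tested, except that a dye term leaves 1 residual degree of freedom.

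STI571 against untreated had 0 calls, and 4 without centring, 8 with robust statistics, 8 at a threshold of 0.1, 787 by the 1.5-fold rule (624 positive, against 101 the same way by dye) and 0 to 72 with 1 array left out (72 without STI571 array 1, 9 without STI571 array 2). It had 0 under each other alternative run for it. AMI+STI571 against AMI had 1 call, and 0 with the dye term (the replicate block), scaling, 1 value per pair, unmoderated statistics, run centring and ratios already turned. It had 486 by the 1.5-fold rule (403 positive, 88 by dye) and 0 to 5 with 1 array left out (5 without AMI+STI571 array 1, 0 without each other), and 1 under each other alternative run for it. The difference had 0 calls under each alternative run for it but the left-out arrays, with 0 to 15 (15 without STI571 array 1).

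The mean had 16 calls, and 3 with scaling, 6 with 1 value per pair, 38 with robust statistics, 0 unmoderated, 595 at 0.1 (496 positive, 99 negative), 6 with treat, 191 by the 1.5-fold rule (180 positive, 4 by dye), 5 with run centring, 0 with ratios already turned and 0 to 75 with 1 array left out (75 without STI571 array 1, 0 without AMI+STI571 array 2, 7 without AMI+STI571 array 1, 3 without STI571 array 2). The replicate block, a dye term, gave 12, of which 10 were among the 16, without CYB5R2 and TOR1AIP2. It was 19 without centring (all 16 kept), 14 with neighbouring calls counted once, and 16 with exact zeros missing and with each probe alone. The rank correlation of 0.586 was 0.027 with ratios already turned, 0.384 to 0.554 with 1 array left out, and 0.565 to 0.621 otherwise. Lists past camera were 0, or 0 to 1 with 1 array left out.

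With ratios already turned, the mean was -0.015 for WAC, -0.016 for CYB5R2, and -0.164, -0.403, -0.048, -0.178, -0.152 and -0.076 for probes 12116, 18084, 3681, 4203, 6603 and 8765. Without centring, the mean turned for CASP10 (-0.023), AIFM1 (-0.017), MXD4 (-0.051), MT1E (-0.032), MT1G (-0.08), RRP9 (-0.082), PES1 (-0.104), NCL (-0.104), POLR1B (-0.101), H2AC6 (-0.05), ABCC3 (-0.166) and B2M (-0.097), and the difference for BMF (0.04). In that setting the median of all features is -0.272 for STI571, -0.117 with AMI and -0.194 for the mean, against 0.002, 0.012 and 0.008 with centring. Run centring turned the mean of RRP9 (-0.007), ISG20 (-0.008) and ABCC3 (-0.044).

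With 1 array left out, the difference turned without STI571 array 1 for BCL2L11 (range -0.028 to 2.483), BOK (-0.506 to 0.154), CASP4 (-0.121 to 0.412) and DAXX (-0.396 to 0.851), and without STI571 array 2 for BMF (-0.414 to 0.203), HTRA2 (-0.29 to 0.548) and PARP1 (-0.27 to 0.492). The mean turned without STI571 array 1 for BMF (-0.265 to 0.044), MT2A (-0.333 to 0.034), POLR1B (-0.036 to 0.238), ABCC3 (-0.06 to 0.132) and B2M (-0.005 to 0.214). Without AMI+STI571 array 1 it turned for SESN2 (-0.254 to 0.022), POLR1B, H2BC21 (-0.991 to 0.031), H2AC6 (-0.055 to 0.358) and ABCB1 (-0.41 to 0.089), and without array 2 of that comparison for ABCC3. None of the genes that turned under centring, run centring or left-out arrays had passed the threshold.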

Other observations

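All tests in this part were chosen after the results were seen, and signs are those of the report, positive meaning higher with STI571 if the ratios are Cy5 over Cy3. Genes whose separate probes gave like values were looked for, and those named here were chosen after their values were seen. HJURP, a chaperone of the centromeric histone, had 1.11 ± 0.11 over 3 probes in the mean of both comparisons, with 1.02 ± 0.16 without AMI and 1.19 ± 0.16 with it, and it was positive on 4 of 4 arrays. NDUFS7, a subunit gene of respiratory complex I, had 1.06 ± 0.19 over 2 probes, and LMO7 had 0.85 ± 0.11 over 2. None passed the threshold over all features, with adjusted p of 0.0718 for HJURP, 0.0938 for NDUFS7 and 0.0823 for LMO7.

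The ratios changed sign with the dye orientation, which a treatment effect in ratios that follow the dyes would give. A dye effect of single probes in ratios already turned by the authors would give it too. In that case, and without an effect of position, 2 probes of the same gene more than 300 numbers apart would not be related. Over 1724 such pairs their rank correlation was 0.151 (95% bootstrap interval 0.104 to 0.198), and 0.04 (-0.007 to 0.085) for the part that keeps its sign. The gap between these correlations was 0.111 (95% bootstrap interval 0.047 to 0.181). But probes 400 and 1200 numbers apart, whatever their gene, had 0.198 and 0.179 in the part that changes sign. In the part that keeps its sign they had 0.133 and 0.082, so position alone also gave a gap. These distances were not matched to those of the pairs. The 0.151 therefore decides nothing about probe-specific dye effects, as probes paired by number alone gave values as high. A dye effect that follows transcript abundance stays open: the 24 ribosomal protein genes, which are abundant, had a median of 0.024 with 12 on either side, and members that go both ways decide nothing. An effect of STI571 on the RNA stays open too.

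Large positive ratios stood next to each other. Of the 229 probes above 1, 39.7% had another within 2 numbers, against a median of 4.4% and at most 11.4% in 1000 random placements. Of the 85 probes below -1 it was 9.4%, against a median of 2.4% and at most 11.8% in random placements. That lies within the random range but near its upper end, so clustering of negative probes is not excluded. DNA or signal shared between neighbouring spots is a candidate explanation. A change in the RNA of the named genes would also show in their other probes, if those measure the same RNA. For 37 genes with another probe over 300 numbers away, the median of those other probes was -0.008 (95% bootstrap interval -0.096 to 0.139, SD between genes 0.41). The large ones had 1.21, and 5 of the 37 exceeded 0.5. The large ratios were thus mostly not repeated by other probes. That does not decide against a change in the RNA. The large probes were picked by size, and 2 probes of 1 gene were only weakly related in general (rank correlation 0.151). Other probes can also fail or match other transcripts, and the genes called here, WAC, ARRDC1, CYB5R2 and TOR1AIP2, have 1 probe each and stay open.

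The 7 measured globin genes were all positive in the mean of both comparisons, from 0.155 to 0.305 (median 0.26), as with scaled arrays and run centring, but 5 of 7 were without centring (median 0.06). On all 4 arrays 3 of them were positive, and as high a median came up in 268 of 10000 random lists of 7 genes. A hypothesis of a shift of erythroid transcripts as a group was set against the other 22 erythroid genes, which had a median of -0.087, 10 positive and 12 negative (SD 0.46), so it cannot be told from these members. Cross-hybridisation between globin probes may contribute: the 21 probes differed no more between genes than under random naming (permutation p = 0.995, one-sided), which a common change of globin RNA would give as well.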
